A study of Mus musculus with 13 samples.

How the data were processed

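RNA was sequenced from 13 libraries of mouse skeletal muscle cells of mixed strain. Per the labels, primary myoblasts came from the hind limbs of pups at postnatal day 2 to 3, and myotubes were the same kind of cells after 24 hours in medium with 1% horse serum. The cells were wild type or dICR/dICR, homozygous for a deletion of the imprinting control region that lies between Igf2 and H19. RNA with an integrity number over 9 was depleted of ribosomal RNA. The labels describe 2 sequencing platforms, an Illumina instrument with paired reads of 101 bases and SOLiD with paired reads of 35 and 75 bases. Which library was run on which platform is not given in the sources used here. The labels also do not say whether replicates were separate cultures or animals, or whether a myotube library came from the same culture as a myoblast library, so the p-values measure only the spread between the samples. The series description gives 2 to 3 replicates per group, whereas the table holds 4 wild-type myoblast and 5 wild-type myotube libraries, and all 13 were used as labelled.

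The deposited table holds raw counts per gene and library, with no normalisation. Per the submitters' processing notes, reads were aligned with TopHat2 to the mm9 assembly and counted with HTSeq. The versions, the gene annotation, the counting mode and the strand setting are not given in the sources used here. The table lists 23366 genes by symbol. Of these, 21525 matched a current symbol of the reference annotation and 23207 matched a symbol or a synonym. There were 27 names in the form of dates, of which 2 occurred more than once, and these were left as deposited. The reference annotation is of a later assembly than mm9, so genes are given by symbol and by their order along chromosome 7, without positions. Counts of genes that overlap on opposite strands, Igf2 with Igf2as and Kcnq1 with Kcnq1ot1, are uncertain, since the strand setting is not known.

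Total counts per library ranged from 5.31 to 56.44 M (mega) counts. They fell in 2 sets with no library between 10.91 and 35.56 M, and these are called the deep set (7 libraries) and the shallow set (6 libraries), divided at 20 M counts. The sets were defined from the data and are not groups of the study. That a technical batch, if one were seen, would enter as a term and by contrasts within it was fixed in advance. The dICR/dICR libraries of each cell type lie in 1 set, the 2 myoblasts in the shallow set and the 2 myotubes in the deep set. Wild-type myoblasts have 2 deep and 2 shallow libraries and wild-type myotubes 3 deep and 2 shallow. No 2 replicate libraries held the same counts throughout, and chi-square per degree of freedom between replicates, over genes with at least 10 counts, ranged from 4.7 to 370.6, so the spread between replicates exceeded counting error in each pair.

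Counts were analysed in R 4.3.3. Genes were kept with edgeR 4.0.16 filterByExpr by group (minimum count 10, minimum total 15), which left 16537 genes. TMM factors were used, and 1 quasi-likelihood model with 4 group means was fitted to all 13 libraries, so that the pairs of dICR/dICR libraries share the spread estimated in the larger groups. The 6 contrasts were the genotype effect (dICR/dICR minus wild type) in myoblasts and in myotubes, differentiation (myotubes minus myoblasts) in wild type and in dICR/dICR, the difference between these 2 differentiation changes, and the genotype effect averaged over cell types. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are given with their standard errors (SE), and levels as CPM (counts scaled to a common total after adjusting each library total by its TMM factor), with the standard deviation (SD) between libraries. CPM and log values per library used a prior count of 2 where a log was taken. The same contrasts were fitted with the depth set as an additive term, which takes the shift between sets from the wild-type libraries, and within each set that holds both groups of a contrast. No set holds both dICR/dICR groups, so differentiation in dICR/dICR has no value within a set.

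Gene lists were written from textbook knowledge before the data were examined, as were the 6 contrasts, the edgeR and list tests on them, and the rule for named genes. Tests and settings chosen later are named in the closing section. The 21 lists are the distal chromosome 7 cluster, imprinted genes outside it, proliferating myoblast and satellite cell genes, myogenic differentiation and fusion, sarcomere and excitation-contraction coupling, cell cycle, p53 targets, ERK pathway output, insulin-like growth factor, AKT and mTOR signalling, atrophy and FoxO targets, the transforming growth factor beta and BMP pathway, integrated stress and heat shock, markers of fibroblasts and fibro-adipogenic cells, adipocytes, endothelium, macrophages and leukocytes, Schwann cells and nerve, smooth muscle and pericytes, and erythroid cells, nuclear long noncoding RNAs, and sex-linked check genes. The erythroid list had 2 tested members and no list test was run on it. The other 20 lists were tested with limma 3.58.1 camera on log2 CPM, with a preset correlation between genes of 0.01, and again with an estimated correlation. The fry test was run as an alternative. P-values of list tests were adjusted over the lists within a contrast. Members called are counted over all genes tested and also adjusted over the list alone.

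The rule for named genes takes, in each contrast of 2 groups, the 10 rising and 10 falling genes with the largest log2 fold change among those called, with a mean log2 CPM of at least 2 over all libraries and no overlap between the libraries of the groups compared. For the difference between the differentiation changes and for the averaged genotype effect it takes 5 in each direction, without the condition on overlap. It also takes every tested member of the distal chromosome 7 cluster, and from each other list up to 4 members with the smallest p-values. Unnamed genes and genes for microRNAs and small nucleolar RNAs were passed over.

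Correlations between contrasts are across 16537 genes, which are not independent replicates. Where the genotype effect in myotubes is set against differentiation in wild type, both contrasts use the wild-type myotubes. These libraries were therefore divided between the contrasts in each of the 10 ways. From 100 simulations of unchanged groups came the value to be seen with no effect and with genes varying independently. On data simulated with 100 genes changed 4-fold, the model without a depth term recovered 12 of 100 genes in myoblasts, 22 in myotubes, 40 for differentiation in wild type and 0 for differentiation in dICR/dICR, with at most 2 false calls. With the depth set as a term it recovered 47, 56, 57 and 22 of 100, with at most 6 false calls. For genes changed 2-fold the model without the term recovered 0, 0, 7 and 0 of 100. These simulations give genes no correlation with one another. Alternatives tried were RLE factors, library size alone, DESeq2 1.42.0, limma voom with sample weights, no low-count filter, a filter of 1 CPM in 4 libraries, thinning to the smallest library (seed 1), a model of only the groups compared, a block by replicate number, the depth set, 1 surrogate variable from sva 3.50.0, a test against a log2 fold change of 1, and leaving out each library in turn. No library and no column was left out of the design.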

Results

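The data are RNA-seq counts for 13 libraries in 4 groups: wild-type myoblasts (n = 4), wild-type myotubes (n = 5), dICR/dICR myoblasts (n = 2) and dICR/dICR myotubes (n = 2). Total counts, in mega (M) counts, were 54.54, 51.67, 6.95 and 5.55 M in wild-type myoblasts 1 to 4 and 35.56, 36.46, 48.78, 6.52 and 5.31 M in wild-type myotubes 1 to 5. They were 10.91 and 6.33 M in dICR/dICR myoblasts and 56.44 and 43.26 M in dICR/dICR myotubes. Between 16208 and 20313 genes had a count in each library. The deep and shallow libraries differed in more than depth: genes for small nucleolar RNAs took 0.028 to 0.177% of counts in the 7 deep libraries and 2.813 to 7.185% in the 6 shallow ones. In wild type, 3649 genes differed between shallow and deep myoblasts and 2204 between shallow and deep myotubes, of which 1453 were the same genes with the same direction. Sarcomere genes were among the differences: their mean log2 CPM was 5.81 and 5.79 in wild-type myoblasts 1 and 2 (deep), and 7.61 and 7.64 in 3 and 4 (shallow). The Y-linked gene Ddx3y stood between 0.15 and 0.46 CPM in the 4 shallow wild-type libraries and between 14.54 and 176.05 CPM in the other 9. Because the dICR/dICR myoblasts are all shallow and the dICR/dICR myotubes all deep, each genotype effect is given over all libraries and within the set that holds both genotypes.

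**Figure D1:**
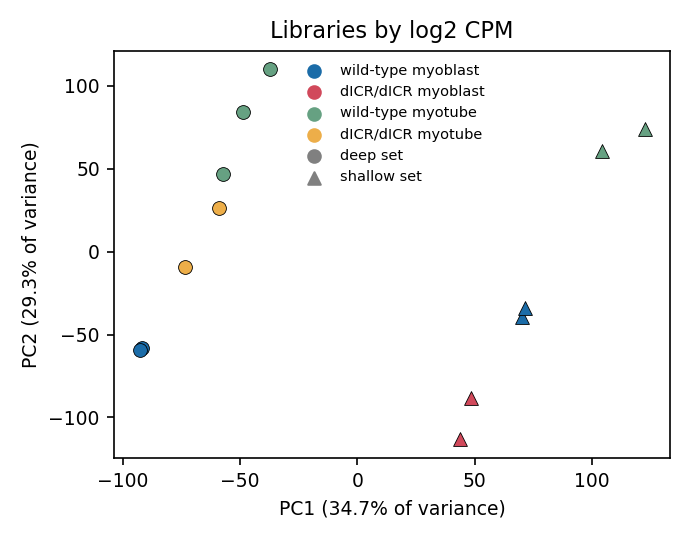
Principal components of log2 CPM for the 13 libraries, with component 1 (34.7% of the variance) on the horizontal axis and component 2 (29.3%) on the vertical axis. Deep libraries have negative and shallow libraries positive values of component 1, and within each genotype the myotubes lie above the myoblasts on component 2.

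The first comparison asks what the deletion did to the genes beside it. H19, the long noncoding RNA of the locus, fell from a mean of 26600 CPM in wild-type myotubes (SD 9680, n = 5) to 55 CPM in dICR/dICR myotubes (SD 3.56, n = 2), a log2 fold change of -8.92 ± 1.21 (adjusted p = 0.0143, edgeR quasi-likelihood with Benjamini-Hochberg). In myoblasts H19 stood at 10200 CPM in wild type (SD 8970, n = 4) and 62.7 CPM in dICR/dICR (SD 12.6, n = 2). That log2 fold change of -7.35 ± 1.13 did not pass over all libraries (adjusted p = 0.0562, edgeR quasi-likelihood), where wild-type myoblasts held 2606.66 and 2344.96 CPM in the deep set and 18489.01 and 17484.79 CPM in the shallow set. It passed within the shallow set, at -8.17 ± 0.52 (adjusted p = 5.35e-05, edgeR quasi-likelihood), and the myotube value within the deep set was -8.60 ± 0.52 (adjusted p = 3.16e-05). Each dICR/dICR library held less H19 than each wild-type library. Igf2, the fetal growth factor gene on the other side of the region, had log2 fold changes of 0.47 ± 0.74 in myoblasts (adjusted p = 0.812, edgeR quasi-likelihood) and 1.47 ± 0.68 in myotubes (adjusted p = 0.303), neither past the threshold. Its level was 2630.11 and 8294.24 CPM in the 2 dICR/dICR myotube libraries against 1350 to 2550 CPM in the 5 wild-type ones, and 1571.3 and 578.61 CPM in dICR/dICR myoblasts against 188 to 1460 CPM. Within a set the Igf2 values were -0.27 ± 0.56 in shallow myoblasts (adjusted p = 0.834, edgeR quasi-likelihood) and 1.65 ± 0.50 in deep myotubes (adjusted p = 0.0925).

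Without dICR/dICR myotube 1 the H19 and Igf2: H19, genotype effect in myotubes was -8.99 (adjusted p = 0.412, edgeR quasi-likelihood), and without dICR/dICR myotube 2 it was -8.86 (adjusted p = 0.0796), each leaving 1 dICR/dICR library that is assumed to vary like the others. For Igf2, the H19 and Igf2: Igf2, genotype effect in myotubes was 0.41 without dICR/dICR myotube 2, and the H19 and Igf2: Igf2, genotype effect in myoblasts was -0.43 without dICR/dICR myoblast 1, so the sign in myoblasts rests on that library.

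**Figure D2:**
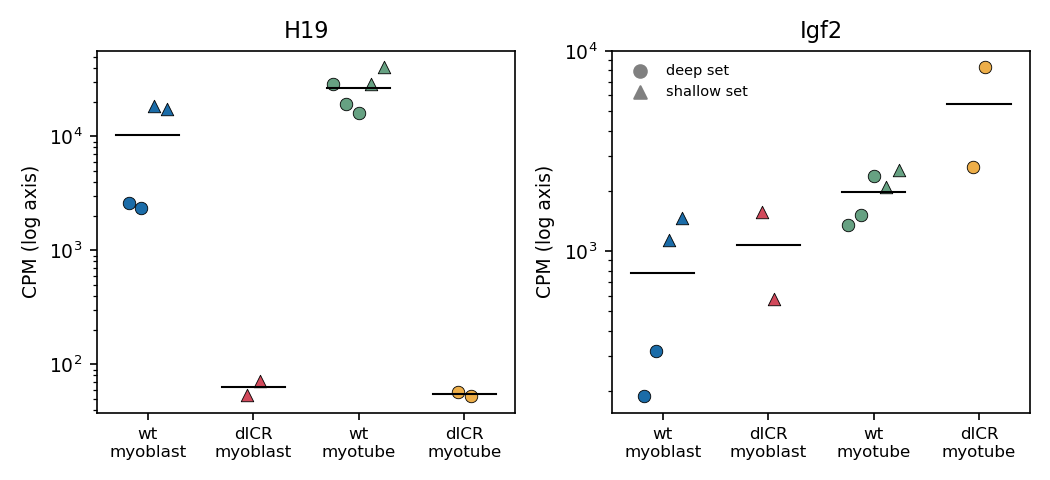
CPM (log axis) of H19 and Igf2 in each of the 13 libraries by group, with deep libraries as circles, shallow libraries as triangles and the group mean as a black line. The 4 dICR/dICR libraries hold 52.44 to 71.54 CPM of H19, and the 9 wild-type libraries hold 2344.96 to 40495.16 CPM.

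The genotype effect in myoblasts asks what differs before differentiation. Mecom, a zinc finger transcription factor gene, was higher in dICR/dICR myoblasts, at 46 CPM (SD 8.12, n = 2) against 12.4 CPM (SD 0.768, n = 4), a log2 fold change of 1.89 ± 0.25. Urb1, a ribosome biogenesis gene, was higher by 1.32 ± 0.19 on the log2 scale. Mtus1, a microtubule-associated tumour suppressor gene, stood at 1.21 CPM against 15 CPM, a log2 fold change of -3.62 ± 0.51, and Akip1, which encodes a partner of protein kinase A, was also lower, at -2.35 ± 0.33. These 4 and Igsf5 had the same adjusted p = 0.0459 (edgeR quasi-likelihood, Benjamini-Hochberg). Igsf5 (log2 fold change 5.33 ± 0.67) falls outside the rule for named genes and was chosen after its values were seen. Over all libraries 5 genes were called, 3 higher and 2 lower, with 2009 at an unadjusted p under 0.05. Within the shallow set (2 against 2 libraries) 868 genes were called, 321 higher and 547 lower, and all 5 were among them with the same direction. In this comparison genotype coincides with Y-linked expression: Ddx3y stood at 0.25 and 0.15 CPM in wild-type myoblasts 3 and 4 and at 14.54 and 63.07 CPM in dICR/dICR, so the myoblast values within the shallow set cannot be separated from the sex of the pups or the animals used. The fit with the depth set as a term called 333, of which 121 were higher.

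By gene list, muscle genes had lower means in dICR/dICR than in wild-type myoblasts, mainly against 3 and 4, of the same depth set. The mean log2 CPM of the sarcomere list was 6.06 and 5.34 in dICR/dICR against 5.81 and 5.79 in wild-type myoblasts 1 and 2 and 7.61 and 7.64 in 3 and 4, and that of the myogenic differentiation list 5.41 and 4.88 against 5.43 and 5.47, then 6.46 and 6.46. Without wild-type myoblasts 3 and 4, a setting chosen after the data were seen, the medians of the 2 lists turned to 0.11 and 0.05 (camera adjusted p = 0.807 for both), and the replicate block also ended both calls (0.18 for both). Over all libraries all 52 sarcomere and excitation-contraction coupling genes had negative values, with a median log2 fold change of -1.16 (camera adjusted p = 4.13e-07, but adjusted p = 0.635 with an estimated correlation). None was called over all genes by edgeR, and 4 fell when adjusted over the list alone: Myl1 (-2.14), Cryab (-2.44), Cacng1 (-2.15) and Myh1 (-3.42). Within the shallow set 23 of the 52 fell, or 42 adjusted over the list alone, with a median of -1.89 (camera adjusted p = 1.93e-22, and adjusted p = 0.177 with an estimated correlation). The muscle creatine kinase gene Ckm (-3.55 ± 0.48), the skeletal actin gene Acta1 (-2.53 ± 0.36) and the fast troponin genes Tnnt3 (-2.57 ± 0.31) and Tnni2 (-2.66 ± 0.27) were among them. The myogenic differentiation and fusion genes had a median of -0.89 (camera adjusted p = 6.86e-05, and adjusted p = 0.635 with an estimated correlation), with 0 of 30 called by edgeR and 2 fallen when adjusted over the list alone, Cdkn1c (-4.49 ± 0.74) and Dysf (-2.11 ± 0.45). Within the shallow set 12 of the 30 fell, Rbm24, Stac3 and Jsrp1 among them, at -1.70, -1.43 and -1.58 (list adjusted p = 0.177 with an estimated correlation). The p53 target list had a median of -0.83 (camera adjusted p = 1.05e-06, and adjusted p = 0.635 with an estimated correlation) with 0 of 29 called, and within the shallow set Ptprv, Bax, Perp and Gadd45a fell. The p53 median was -1.51 without dICR/dICR myoblast 1 and -0.37 without dICR/dICR myoblast 2, and the myogenic median -0.58 without the latter. The proliferating myoblast list had a median of -0.60 (camera adjusted p = 0.0396, and adjusted p = 0.635 with an estimated correlation) with 0 of 24 called, a list call lost without any 1 of 7 libraries. Cell-cycle genes had a median of 0.56 with no list call over all libraries (camera adjusted p = 0.0776). Within the shallow set 34 of 35 were positive, with a median of 1.15 (camera adjusted p = 0.000486, and adjusted p = 0.782 with an estimated correlation), and 0 were called.

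In the distal chromosome 7 cluster the growth-inhibitor gene Cdkn1c stood at 3.24 CPM in dICR/dICR myoblasts against 73.3 CPM. Its log2 fold change of -4.49 ± 0.74 did not pass over all libraries (adjusted p = 0.0725, edgeR quasi-likelihood), and it passed within the shallow set at -3.86 ± 0.66 (adjusted p = 0.00951). Mrpl23 fell within the shallow set by 1.48 ± 0.33 on the log2 scale (adjusted p = 0.0269, edgeR quasi-likelihood), as did Tnnt3 and Tnni2, which also lie in this cluster. The other measured members, Igf2as, Nctc1, Tspan32, Cd81, Tssc4, Trpm5, Kcnq1, Kcnq1ot1, Slc22a18, Nap1l4, Cars, Lsp1, Syt8 and Ctsd, had values between -4.63 (Slc22a18) and 1.53 (Igf2as) over all libraries, and none passed. The Slc22a18 value rests on wild-type myoblasts 1 and 2 (3.431 and 5.635 CPM), as it stood at 0 CPM in 3 and 4 and at 0.1563 and 0 CPM in dICR/dICR, too few counts for a direction within the shallow set. The list as a whole was not called (median -0.48, camera adjusted p = 0.0745). The count of 5 over all libraries fell to 0 without any 1 of the 4 wild-type myoblasts, dICR/dICR myoblast 2, either dICR/dICR myotube, or wild-type myotubes 3 or 4. It was 1 without dICR/dICR myoblast 1 and 2 without wild-type myotube 5, and DESeq2 called 432 and limma voom 3320.

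The genotype effect in myotubes asks what differs 24 hours after the change of medium. The heat shock gene Hspb8 was lower in dICR/dICR myotubes, at 5.28 CPM (SD 4.72, n = 2) against 700 CPM (SD 509, n = 5), a log2 fold change of -7.05 ± 1.11 (adjusted p = 0.0237, edgeR quasi-likelihood, Benjamini-Hochberg). Pgm5, which encodes a protein of muscle cell adhesions, fell by 3.52 ± 0.62 (adjusted p = 0.035), the butyrylcholinesterase gene Bche fell by 3.72 ± 0.55 (adjusted p = 0.0181), and Zfp105 fell by 4.24 ± 0.50 (adjusted p = 0.00729). The hedgehog-binding protein gene Hhip was higher, at 45.2 CPM (SD 23) against 1.36 CPM (SD 0.746), a log2 fold change of 5.01 ± 0.66 (adjusted p = 0.0134). Sigirr, an inhibitor of interleukin-1 signalling, was higher by 5.36 ± 0.88 (adjusted p = 0.0266), the lysophosphatidic acid receptor gene Lpar2 by 3.2 ± 0.34 (adjusted p = 0.0049), and the phosphodiesterase gene Pde3b by 3.03 ± 0.48 (adjusted p = 0.0237).

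Over all libraries 92 genes were called, 55 higher and 37 lower, with 2773 at an unadjusted p under 0.05. With library size alone the split was 65 and 19 of 84. The other genes named by the rule were Osbp2, Tmprss11f, Itgb7, Kbtbd11, Smpd3 and Tcerg1l, higher by 3.05 to 4.20, and Adamtsl2, Tceal3, Ramp1, Fam213b and Gldc, with values from -4.92 to -2.75. Within the deep set (2 against 3 libraries) 601 genes were called, 299 higher and 302 lower, and with the depth set as a term 425. All 92 were among both with the same direction. Within the deep set Hspb8 stood at -6.57 ± 0.94 (adjusted p = 0.00564, edgeR quasi-likelihood), Sigirr at 5.40 ± 0.58 (adjusted p = 0.000924) and the titin-binding gene Ankrd2 at -5.21 ± 0.56 (adjusted p = 0.000924).

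All 35 cell-cycle genes were higher in dICR/dICR myotubes, with a median log2 fold change of 2.44 (camera adjusted p = 4.64e-22, but adjusted p = 0.53 with an estimated correlation). Of them 1 rose over all genes, the cyclin E gene Ccne1 (2.24 ± 0.40, adjusted p = 0.035, edgeR quasi-likelihood), and 28 when adjusted over the list alone. Within the deep set the median was 1.95 (camera adjusted p = 6.37e-16, and adjusted p = 0.671 with an estimated correlation), and 3 rose: Ccne1, the replication helicase gene Mcm7 (1.40 ± 0.34) and Pcna (1.84 ± 0.45). The wild-type myotubes differed among themselves here: their mean log2 CPM over the list was 3.59, 5.91, 2.47, 2.67 and 2.18 in libraries 1 to 5, against 7 and 5.99 in the dICR/dICR myotubes. Sarcomere genes were lower, with 51 of 52 negative and a median of -1.16 (camera adjusted p = 5.14e-08, but adjusted p = 0.587 with an estimated correlation). None was called by edgeR over all genes or adjusted over the list alone. Within the deep set the median was -0.78 (camera adjusted p = 2.04e-05, and adjusted p = 0.671 with an estimated correlation), the calcium channel subunit gene Cacng1 (-2 ± 0.35) and Acta1 (-1.31 ± 0.32) fell, and the fast-fibre actinin gene Actn3 rose (3.2 ± 0.39). The myogenic differentiation list had a median of -0.56 (camera adjusted p = 0.00021, and adjusted p = 0.587 with an estimated correlation). The membrane-repair gene Dysf was the member that fell over all genes (-2.52 ± 0.45), and 4 fell when adjusted over the list alone. Without dICR/dICR myotube 1 and then without dICR/dICR myotube 2 the myogenic median was -0.27 and -1.1, the sarcomere median -0.76 and -1.75 and the distal chromosome 7 median -0.49 and -1.2, and the cell-cycle median was 3.96 without wild-type myotube 2. The replicate block ended the calls of the sarcomere, myogenic and distal chromosome 7 lists (camera adjusted p = 0.365, 0.146 and 0.0607).

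The distal chromosome 7 list was lower in dICR/dICR myotubes, with a median of -0.75 (camera adjusted p = 0.00025, and adjusted p = 0.53 with an estimated correlation). H19 was the 1 of 20 that fell over all genes, and 4 fell when adjusted over the list alone. Cdkn1c had a log2 fold change of -3.00 ± 0.66 over all libraries (adjusted p = 0.0683, edgeR quasi-likelihood) and fell within the deep set, at -3.22 ± 0.58 (adjusted p = 0.0148). Syt8 also fell there (-2.92 ± 0.68), and Igf2as, which overlaps Igf2 on the other strand, rose (1.66 ± 0.31, adjusted p = 0.0181). The members other than these and Igf2 ranged from -2.40 (Nctc1) to 0.61 (Mrpl23) over all libraries and did not pass. The transforming growth factor beta and BMP list had a median of -0.60 (camera adjusted p = 0.00257, and adjusted p = 0.224 with an estimated correlation), and Skil, Tgfb3 and Grem1 fell within the deep set. Fibroblast markers had a median of -1.37 (camera adjusted p = 0.0124, and adjusted p = 0.587 with an estimated correlation), a call lost without dICR/dICR myotube 2 (camera adjusted p = 0.208) or wild-type myotubes 2 or 3, with a median of -2.1 without dICR/dICR myotube 1. The p53 list was not called (median -0.34, from -0.88 to 0.12 with 1 library left out), although the fructose bisphosphatase gene Tigar, listed as 9630033F20Rik, rose by 1.43 ± 0.21 and Gtse1 by 1.80 ± 0.33. The noncoding RNA Snhg1 rose by 2.05 ± 0.34.

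The count of 92 was 1 without dICR/dICR myotube 1, 17 without wild-type myotube 3, 22 without dICR/dICR myotube 2, 31 without wild-type myotube 4, 43 without wild-type myotube 5 and 919 without wild-type myotube 2. It was 38, 40, 47 and 42 without wild-type myoblasts 1 to 4 and 52 without either dICR/dICR myoblast.

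**Figure D3:**
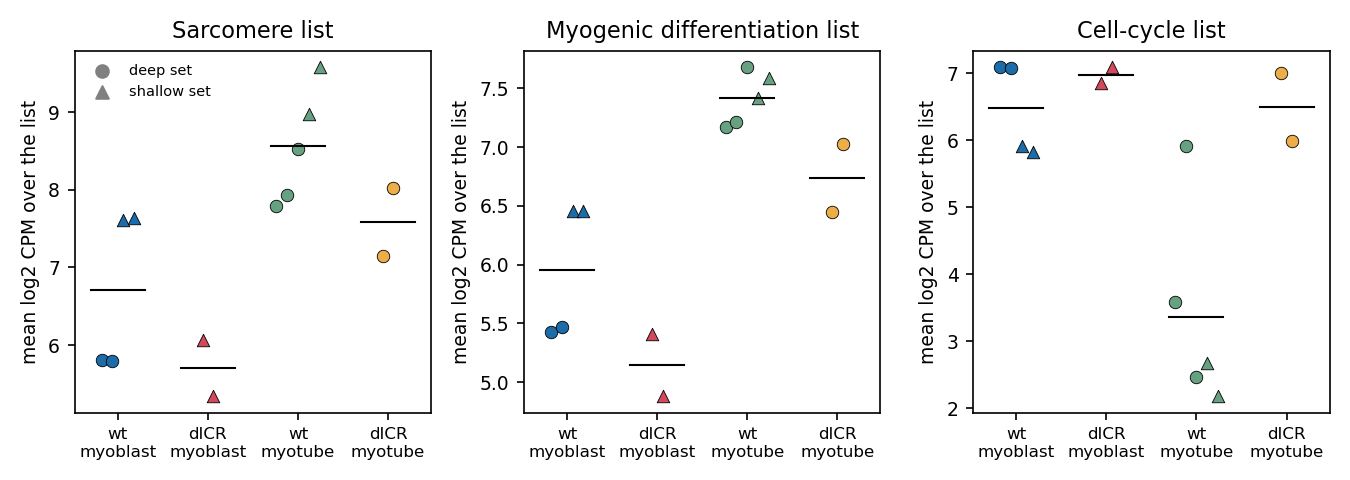
Mean log2 CPM over the members of gene lists in each library by group, with deep libraries as circles, shallow libraries as triangles and the group mean as a black line. In the cell-cycle list the dICR/dICR myotubes lie at 7 and 5.99 and the wild-type myotubes between 2.18 and 5.91.

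Differentiation in wild type asks which genes change as myoblasts become myotubes. Muscle genes rose: 30 of 52 sarcomere genes passed, or 37 adjusted over the list alone, with a median log2 fold change of 1.97 (camera adjusted p = 4.91e-16, but adjusted p = 0.345 with an estimated correlation). The cardiac actin gene Actc1 rose by 3.59 ± 0.61 (adjusted p = 0.0029, edgeR quasi-likelihood, Benjamini-Hochberg), Mybph by 2.52, Cacng1 by 2.49 and the myosin light chain gene Myl1 by 1.91. Of the myogenic differentiation genes 19 of 30 rose, with a median of 1.55 (camera adjusted p = 1.84e-09, and adjusted p = 0.345 with an estimated correlation), or 22 adjusted over the list alone, where 1 fell. Dysf rose by 2.37 ± 0.33, the histone deacetylase gene Hdac9 by 2.53 and the adhesion gene Jam3 by 1.71. Cell-cycle genes fell, 19 of 35 over all genes and 29 adjusted over the list alone, with a median of -2.27 (camera adjusted p = 1.93e-16, and adjusted p = 0.345 with an estimated correlation), among them Ccnd1 (-4.39 ± 0.36), Ccne2 (-2.74), Mcm2 (-2.17) and Ccne1 (-2.10). The cell-cycle median was -3.81 without wild-type myotube 2 and -3.59 within the shallow set, the myogenic median 2.38 within the deep set, and the sarcomere median 3.31 without wild-type myoblasts 3 and 4.

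By single genes the ryanodine receptor gene Ryr3 rose from 3.6 CPM (SD 1.89, n = 4) to 76.7 CPM (SD 32.1, n = 5), a log2 fold change of 4.47 ± 0.45 (adjusted p = 0.00029, edgeR quasi-likelihood), and C1qtnf3, a secreted C1q-domain protein gene, from 77.6 to 1540 CPM. Cyp1b1 (7.20 ± 1.03), Adamtsl2 (4.94 ± 0.72), Islr, Dpp6, Ctrb1, Flrt1 and Medag also rose. Wisp2 stood at 0 CPM in wild-type myoblasts 1, 3 and 4, at 0.0777 CPM in myoblast 2 and between 0.923 and 59.9 CPM in myotubes. The neurofilament genes Nefl (-7.06 ± 0.88, from 212 to 1.52 CPM) and Nefm (-5.14 ± 0.88) fell, as did the cytokine gene Il33 (-5.68 ± 0.84), the apelin gene Apln (-5.95 ± 0.78) and Eps8 (-4.66 ± 0.62). Hhip (-5.28 ± 0.63), Osbp2 (-4.80 ± 0.47) and Tmprss11f (-4.79 ± 0.67), each higher in dICR/dICR than in wild-type myotubes, fell in wild-type differentiation, with Tmem171 and Gzmd. Islr rested on 1 library, wild-type myotube 2, and the Islr, differentiation in wild type value was 2.82 without it.

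Further lists were called in wild-type differentiation. ERK pathway output had 10 of 30 members fallen and 2 risen (median -0.80, camera adjusted p = 0.000436, and adjusted p = 0.446 with an estimated correlation), with the phosphatase gene Dusp4 at -2.50 ± 0.17 and Etv4 at -4.48, and the antagonist gene Spry1 at 2.47. The insulin-like growth factor, AKT and mTOR list had 8 of 33 risen and 1 fallen (median 0.23, camera adjusted p = 0.0102, and adjusted p = 0.345 with an estimated correlation), with Rps6kb1 at 1.04 and Deptor at 1.31 among those that rose and Irs1 (-1.42) the one that fell. Its median was -0.02 with library size alone, 0.49 without wild-type myoblast 3 and 0.6 within the deep set, and the call was lost within the shallow set (median 0.18, camera adjusted p = 0.436). The ERK median was -0.41 within the shallow set. In the p53 list 11 of 29 fell and 2 rose (median -0.71, camera adjusted p = 0.00818, and adjusted p = 0.446 with an estimated correlation). Fibroblast markers rose with differentiation (5 of 16, median 1.39, camera adjusted p = 0.0102, and adjusted p = 0.446 with an estimated correlation), with Postn at 3.90 ± 0.69 and Col1a1 at 5.83. Both list calls were lost without wild-type myotube 2, the p53 list at camera adjusted p = 0.0507 and the fibroblast list at 0.0564, and the latter also within the deep set (0.0962). Smooth muscle and pericyte markers had 4 of 11 risen and 1 fallen (median 1.60, camera adjusted p = 0.0169, and adjusted p = 0.446 with an estimated correlation), with Acta2 at 3.77 ± 0.60 and Rgs5 at -4.99, a list call lost without wild-type myoblasts 1 or 2 or wild-type myotube 2, and within the shallow set (camera adjusted p = 0.178). In the distal chromosome 7 list 4 of 20 rose, Cdkn1c (3.40 ± 0.50), Syt8 (3.91 ± 0.60), Nctc1 (2.18 ± 0.58) and Tssc4 (0.77 ± 0.23), with a list median of 1.00 (camera adjusted p = 0.0001, and adjusted p = 0.345 with an estimated correlation). The list median was 1.84 within the deep set, 0.62 within the shallow set, 0.66 with library size alone and 2.25 without wild-type myoblasts 3 and 4. The other 16 ranged from -3.17 (Slc22a18) to 1.65 (Kcnq1ot1). Among lists that were not called, the satellite cell adhesion gene Vcam1 (-2.34 ± 0.22) and Myf5 (-2.12) fell, Ncam1 (2.23) and the ubiquitin ligase gene Trim63 (3.11 ± 0.60) rose, and 4 of the 24 proliferating myoblast genes rose and 6 fell.

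In total 3158 genes were called, 1466 higher and 1692 lower. Library size alone called 779 higher and 2825 lower, with the median of all genes at -0.256 against 0.02, so the balance of directions depends on the scaling. Within the deep set 4804 genes were called (2369 higher, 2435 lower) and within the shallow set 1154 (616 higher, 538 lower), and 908 were called in both with the same direction. H19 rose in the deep set (3.11 ± 0.40, adjusted p = 0.000286, edgeR quasi-likelihood) and had a value of 0.94 ± 0.38 in the shallow set (adjusted p = 0.158). The count was 1833 without wild-type myoblast 1 and 1769 without wild-type myoblast 2.

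Differentiation in dICR/dICR asks the same of the mutant cells. The cell-cycle inhibitor gene Cdkn1c rose from 3.24 CPM (SD 1.27, n = 2) to 96.8 CPM (SD 37.4, n = 2), a log2 fold change of 4.89 ± 0.79 (adjusted p = 0.0355, edgeR quasi-likelihood, Benjamini-Hochberg). Myl1 rose from 69.9 to 927 CPM (3.73 ± 0.49), the fatty acid binding protein gene Fabp3 by 3.55 ± 0.45 and the dystroglycan gene Dag1 by 3.2 ± 0.46, and the cyclin D1 gene Ccnd1 (-3.44 ± 0.54, from 1220 to 112 CPM) and Dusp4 (-2.68 ± 0.27) fell. Synpo2, Pigp, Adamts5, Ptpla, St3gal5 and Tubb2a rose by 2.60 to 3.55, and Ninl fell by 1.55 ± 0.26. The other genes that fell, Gm5801 (-5.40) and Ndst3 (-3.45), were outside the rule and chosen after their values were seen.

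By list, sarcomere genes were higher in dICR/dICR myotubes than in dICR/dICR myoblasts (median 1.92, camera adjusted p = 6.12e-14, but adjusted p = 0.505 with an estimated correlation), with Myl1 past the threshold and 20 of 52 adjusted over the list alone. Myogenic differentiation genes had a median of 1.91 (camera adjusted p = 1.30e-09, and adjusted p = 0.276 with an estimated correlation), with Cdkn1c past the threshold and 17 of 30 adjusted over the list alone. Cell-cycle genes were not called as a list (median -0.34, camera adjusted p = 0.104), and Ccnd1 was the member that fell. This median was -1.11 without dICR/dICR myotube 1 and 0.09 without dICR/dICR myotube 2, so its sign rests on single libraries. Without the latter the sarcomere median was 1.22. The insulin-like growth factor, AKT and mTOR list (median 0.55, camera adjusted p = 0.000398, and adjusted p = 0.185 with an estimated correlation), the atrophy and FoxO list (1.09, camera adjusted p = 0.00669, and adjusted p = 0.185 with an estimated correlation) and imprinted genes outside distal chromosome 7 (0.54, camera adjusted p = 0.0201, and adjusted p = 0.624 with an estimated correlation) had 0 members called by edgeR, and the last list call was lost without dICR/dICR myoblast 2 or dICR/dICR myotube 2. Without the latter the insulin-like growth factor median was 0.35. With the depth term, in a contrast that runs from shallow to deep, the atrophy median was 0.66, the imprinted median 1.04 and the sarcomere median 3.37. ERK pathway output had Dusp4 and Ccnd1 fallen (median -0.70, camera adjusted p = 0.0124, and adjusted p = 0.696 with an estimated correlation), a list call lost without dICR/dICR myotube 1 (median -0.26, camera adjusted p = 0.428) or dICR/dICR myoblast 1 (0.0692), with a median of -1.19 without dICR/dICR myotube 2.

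In total 24 genes were called, 19 higher and 5 lower, with 3172 at an unadjusted p under 0.05. The myoblasts here are shallow and the myotubes deep, so this contrast also holds the difference between the sets, and the fit that takes that shift from wild type called 1262, 793 higher and 469 lower, with all 24 among them in the same direction. The split of 19 and 5 was 17 and 14 with RLE factors and 11 and 11 with library size alone, which move the median of all genes to -0.126 and -0.286. The count was 0 without dICR/dICR myoblast 1, 1 without dICR/dICR myoblast 2, 3 without dICR/dICR myotube 2, 8, 12, 15 and 16 without wild-type myoblasts 3, 2, 1 and 4, 16 without dICR/dICR myotube 1 and 78 without wild-type myotube 3. Igf2 had a log2 fold change of 2.35 ± 0.91 (adjusted p = 0.209, edgeR quasi-likelihood) and rose with the depth set as a term (3.67 ± 0.87, adjusted p = 0.0253).

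The test of the difference in differentiation between genotypes asks whether the mutant cells change as much as wild type. Cell-cycle genes differed as a list: all 35 had positive values, with a median of 1.78 (camera adjusted p = 3.05e-12, but adjusted p = 0.559 with an estimated correlation), the fall being smaller in dICR/dICR. The dICR/dICR change runs from shallow to deep libraries, and with the depth set as a term the median was 0.70 (camera adjusted p = 0.000263, and adjusted p = 0.624 with an estimated correlation). From the genotype effects within sets, a test added after the data were seen, the difference in the mean log2 CPM of the list was 1.41 ± 1.33. The median over all libraries was 1.09 without dICR/dICR myotube 1 and 3.2 without wild-type myotube 2. The proliferating myoblast list had a median of 0.70 (camera adjusted p = 0.00521) and the p53 list 0.66 (camera adjusted p = 0.00521), both with adjusted p = 0.559 with an estimated correlation. The proliferating myoblast call was lost without wild-type myoblasts 3 and 4 (camera adjusted p = 0.134). The p53 call was lost thinned (median 0.29) and without dICR/dICR myoblast 2 (0.2), dICR/dICR myotube 2 (0.02) or wild-type myotube 2 (0.54). Fibroblast markers had a median of -1.35 (camera adjusted p = 0.0194, and adjusted p = 0.559 with an estimated correlation), a call lost without any 1 of 5 libraries and with the depth term (camera adjusted p = 0.0635), with a median of -2.06 without dICR/dICR myotube 1. The sarcomere and myogenic differentiation lists did not differ past the threshold over all libraries (medians 0.11 and 0.15, camera adjusted p = 0.8 and 0.947, the sarcomere list with the direction down). With the depth set as a term their medians were 0.97 (camera adjusted p = 5.86e-10, and adjusted p = 0.547 with an estimated correlation) and 0.42 (camera adjusted p = 0.0282, and adjusted p = 0.624 with an estimated correlation), and the list means from within sets differed by 1.43 ± 0.55 and 0.70 ± 0.36, with a larger rise in dICR/dICR. No single gene was called by edgeR quasi-likelihood, with 1643 at an unadjusted p under 0.05, and DESeq2 called 57 and limma voom 2. With the depth set as a term 16 genes were called, among them Actn3 (5.19 ± 0.58, adjusted p = 0.00432, edgeR quasi-likelihood), Tnni2 (2.31 ± 0.36, adjusted p = 0.031), Ppp1r14c, Pcdh9 and Tmem181b-ps, with a larger rise or smaller fall in dICR/dICR, and Tor3a (-2.37 ± 0.37). The Y-linked Ddx3y and Eif2s3y were also called, at -8.66 and -9.36. These 2 calls follow from the term, which takes the shift between sets from wild-type libraries, where the shallow ones have almost no Y-linked RNA and the shallow dICR/dICR myoblasts do not share this. The other 14 rest on the same shift, which also carries any difference in the sex of the pups.

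The genotype effect averaged over cell types is the mean of the effects in myoblasts and in myotubes. A call does not mean that a gene differed in both, since either cell type can carry it. Hspb8 was lower in the 4 dICR/dICR libraries, at 4.9 CPM (SD 2.85, n = 4) against 476 CPM (SD 450, n = 9), a log2 fold change of -6.24 ± 0.76 (adjusted p = 0.00329, edgeR quasi-likelihood, Benjamini-Hochberg). H19 stood at -8.14 ± 0.83 (adjusted p = 0.00116), the epidermal growth factor family gene Ereg at -5.76 ± 1.19, the p53 target Perp at -5.23 ± 1.05, and Rprl3, a copy of the RNA gene of ribonuclease P, at -9.52 ± 1.66. Cpne4, which encodes a calcium-dependent membrane-binding protein, was higher, at 76 CPM (SD 65.9) against 3.31 CPM (SD 5.13), with Sigirr (4.10 ± 0.60), Arap3, the fibrillin gene Fbn2 and the integrin gene Itgb7 (3.42 ± 0.49). Sarcomere genes had a median of -1.25 (camera adjusted p = 8.43e-12, but adjusted p = 0.496 with an estimated correlation), with Cacng1, Myh1 and Myl1 fallen. Cell-cycle genes had 35 of 35 positive and a median of 1.47 (camera adjusted p = 1.02e-14, and adjusted p = 0.496 with an estimated correlation), with 0 called by edgeR. The myogenic differentiation list had a median of -0.80 (camera adjusted p = 1.53e-06), with Cdkn1c, Dysf and Cav3 fallen, the p53 list -0.58 (camera adjusted p = 0.00025), with 1 risen and 4 fallen, and the distal chromosome 7 list -0.64 (camera adjusted p = 0.000567), with H19 and Cdkn1c fallen. Each of these 3 had adjusted p = 0.496 with an estimated correlation. The p53 median was -0.95 without dICR/dICR myoblast 1 and -0.25 without dICR/dICR myoblast 2, and without wild-type myoblasts 3 and 4 the sarcomere and myogenic medians were -0.59 and -0.35. The replicate block ended the sarcomere, myogenic and distal chromosome 7 calls (camera adjusted p = 0.127, 0.0888 and 0.121). The transforming growth factor beta list had a median of -0.38 (camera adjusted p = 0.00415, and adjusted p = 0.295 with an estimated correlation).

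In total 398 genes were called, 190 higher and 208 lower (435 and 167 with library size alone), and 2146 within sets, 1079 higher and 1067 lower. The count was 17 without dICR/dICR myotube 1, 19 without dICR/dICR myoblast 2, 159 without dICR/dICR myoblast 1, 225, 226 and 255 without wild-type myoblasts 3, 4 and 1, and 1090 without wild-type myotube 2.

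The genotype effects in myoblasts and myotubes were compared across genes. Over all libraries, Mecom and Igsf5 were the 2 genes higher in both, out of 3 and 55 called (Fisher's exact test, two-sided p = 3.25e-05), and Mtus1 and Akip1 were the 2 lower in both, out of 2 and 37 (p = 4.87e-06). Within sets, 57 genes were higher in both against 5.8 expected (Fisher's exact test p = 3.23e-40) and 90 lower in both against 10 expected (p = 3.24e-61). Hspb8, at -5.89 ± 0.95 in shallow myoblasts and -6.57 ± 0.94 in deep myotubes, Sigirr, at 5.14 ± 0.68 and 5.40 ± 0.58, and Snhg1, at 2.01 ± 0.28 and 1.86 ± 0.24, were among them. The shallow myoblast effect is against wild-type myoblasts 3 and 4 and coincides with Y-linked expression. Agreement within sets therefore cannot be put down to genotype. The log2 fold changes had Pearson r = -0.037 and Spearman rho = 0.07 over all libraries and r = 0.255 within sets. The sign depends on the setting, as r was also above 0 with the 1 CPM filter (0.163), thinned (0.149) and with only the groups compared (0.172). The genotype effects in myoblasts and myotubes compared gave r = 0.098, 0.102, 0.009, 0.023, 0.031 and 0.081 without wild-type myoblasts 1 or 2, wild-type myotubes 2, 4 or 5, or dICR/dICR myoblast 1, and -0.126 and -0.122 without wild-type myoblasts 3 or 4. Genes are not independent replicates, and no p-value is given for these correlations, which are 7 relations of this kind.

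The last comparison asks whether genes that rise on differentiation are lower in dICR/dICR myotubes. Using libraries with nothing in common, deep myotubes for the genotype effect and shallow wild type for differentiation, 92 genes that rose on differentiation were lower in dICR/dICR myotubes, against 11.2 expected (Fisher's exact test p = 8.52e-59), and 85 that fell were higher, against 9.7 expected (p = 1.74e-56). In the same direction there were 3 against 11.1 expected (Fisher's exact test p = 0.00788) and 1 against 9.8 (p = 0.000853). Across genes r was -0.288 and rho -0.359. Over all libraries, with the wild-type myotubes divided between the contrasts, r had a mean of -0.331 over the 10 divisions, from -0.482 to -0.032, against means of -0.001 in simulations of unchanged groups and -0.036 (from -0.053 to -0.014) where these also held the depth sets. The weakest division is no larger in size than the latter. The simulations draw genes independently, so no simulated culture is more or less differentiated as a whole. Their range therefore does not measure variation of that kind between cultures. Hhip, Osbp2 and Tmprss11f were higher in dICR/dICR myotubes and fell in wild-type differentiation, and Adamtsl2 was lower in dICR/dICR myotubes and rose in wild-type differentiation. These genes were named from all libraries, where both contrasts use the same wild-type myotubes with opposite sign. In simulations of unchanged groups this sharing alone gave r = -0.184, so these opposite directions are not separate evidence. In shallow myoblasts 295 genes lower in dICR/dICR rose in deep wild-type differentiation, against 78.4 expected (Fisher's exact test p = 2.19e-109), and 154 higher fell, against 47.3 expected (p = 2.28e-46). In the same direction there were 5 higher in both against 46 expected (Fisher's exact test p = 1.52e-15) and 43 lower in both against 80.5 (p = 1.07e-06). This genotype effect is against wild-type myoblasts 3 and 4, which hold more muscle-gene RNA than 1 and 2, so these overlaps cannot be put down to genotype. These 14 overlaps were tested without adjustment. Fisher's exact test counts genes as independent, so its p-values do not measure the spread between cultures.

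**Figure D4:**
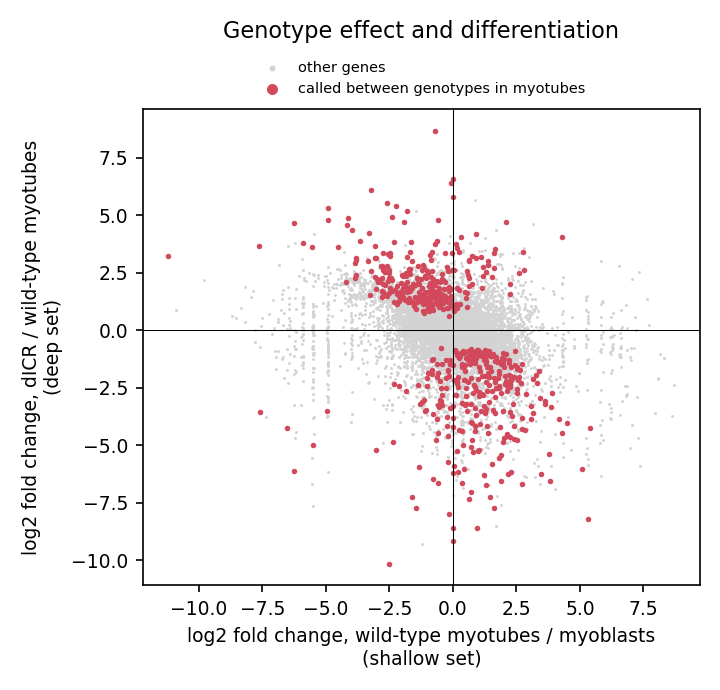
Log2 fold change of each gene for differentiation in shallow wild-type libraries (horizontal axis) and for the genotype effect in deep myotubes (vertical axis). Genes called for the genotype effect in deep myotubes are marked, whether or not they were called for differentiation. Genes called in both contrasts, not marked apart, lie mostly in opposite directions, 92 and 85 against 3 and 1. Across all genes r is -0.288.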

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

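The tests of library preparation, of responses to the sex of the pups, of both explanations for wild-type myoblasts 3 and 4, and of depth sets and fibroblasts for the dICR/dICR myotubes were chosen after the result was seen. The comparison of libraries from opposite depth sets was chosen after the data were seen. Its bound was written before its value was known, as were those of the other tests except as follows. For fibroblasts in the dICR/dICR myotubes a condition on the standard error of the library means was added after the values were known, and by the median and quartile alone this explanation would have been excluded. The rule for depth sets in these myotubes was also rewritten after the values of the cell-cycle genes were known. The muscle genes of these myotubes were divided into the sarcomere and myogenic lists, and the myogenic list was added for wild-type myoblasts 3 and 4, after the values of each list were known, and the 2 lists together exclude nothing in either pattern. For less complete differentiation the condition on the rise of muscle lists was added after its values were known, and by the correlation alone the explanation would have been supported. The sex explanation was narrowed to X- and Y-linked genes after its value was known, with its bounds unchanged.

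The shallow libraries differ from the deep ones in both wild-type cell types, by 3649 genes in myoblasts and 2204 in myotubes, and the change between sets was shared by the cell types (r = 0.637 across genes), as library preparation or sequencing platform would give, so these are a candidate explanation. Transcript length does not account for it (Spearman rho 0.016 in myoblasts and -0.026 in myotubes), and sex of the pups acting through X- and Y-linked genes alone does not, since 96% of the 4377 genes called in either cell type lie on other chromosomes. Sex with responses of other genes as the whole cause is opposed only by dICR/dICR myoblast 2 (Ddx3y 63.07, X-linked Xist 57.47 CPM). There 87.4% of the 2204 myotube genes differed from deep wild-type myoblasts in the shallow direction. Myoblast 1 (Ddx3y 14.54, 88.9%) cannot tell, as Xist was high (428 CPM). Genotype alone does not give the shift. In deep dICR/dICR myotubes 35.1 and 44.3% of the 3649 myoblast genes differed from deep wild-type myotubes that way. GC content stays open at rho 0.171 and 0.172, between the bounds set in advance, and a part played by the sex of the pups, different cultures and different animals stay open and untested, since the labels do not say which library was run on which platform or came from which animals.

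Wild-type myoblasts 3 and 4, both shallow, hold more muscle-gene RNA than 1 and 2, by 1.83 ± 0.40 in the mean log2 CPM of the sarcomere list and 1.01 ± 0.26 in that of the myogenic differentiation list, but not of muscle genes alone, since smooth muscle and pericyte markers (1.73 ± 0.48), nuclear long noncoding RNAs (1.65 ± 0.52) and imprinted genes outside distal chromosome 7 (1.18 ± 0.26) were also higher. For the myogenic list a shift between sets common to both cell types does not account for the whole, since the shift in wild-type myotubes was 0.15 ± 0.24 and the difference of the shifts 0.85 ± 0.36. For the sarcomere list such a shift cannot be told apart from a change in these cultures: the shift in wild-type myotubes was 1.19 ± 0.37, and the difference of the shifts, 0.64 ± 0.55, is under 2 standard errors, as is that of the 2 lists together (0.72 ± 0.47). Partly differentiated cultures could also lower cell-cycle genes, whose mean was 7.09 and 7.08 in wild-type myoblasts 1 and 2 and 5.92 and 5.82 in 3 and 4. The difference of -1.21 ± 0.99 is under 2 standard errors. That error pools the spread of all 13 libraries, with wild-type myotubes from 2.18 to 5.91, and is not the spread of these myoblasts. Partly differentiated cultures stay open as an explanation, as does a shift between sets that differs between cell types, which was not tested.

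The dICR/dICR myotubes had higher medians of cell-cycle genes and lower medians of muscle genes than wild-type myotubes, list calls that do not pass with an estimated correlation (adjusted p = 0.53 for cell cycle and 0.587 for sarcomere and myogenic genes), and the replicate block ended the muscle calls. TMM normalization does not account for the cell-cycle part, as the lower cell-cycle median with library size alone or RLE factors was 2.4 against 2.44, and a difference between depth sets is not the whole cause for the cell-cycle or the myogenic genes, since within the deep set the library means still differed by 2.51 ± 0.90 and -0.61 ± 0.24. For the sarcomere genes, at -0.50 ± 0.37 there, a difference between depth sets cannot be told apart from a genotype effect (-0.54 ± 0.32 for the 2 muscle lists together), and for the whole pattern more fibroblasts stay open, at a median of -1.5 with library means differing by -0.83 ± 0.77, under 2 standard errors. Less complete differentiation in dICR/dICR stays open: the correlation with wild-type differentiation in libraries that share none with it was negative (r = -0.288), but from the values within sets the sarcomere and myogenic lists had larger rises in dICR/dICR, by 1.43 ± 0.55 and 0.70 ± 0.36. These take the myoblast effect against wild-type myoblasts 3 and 4, whose high muscle-gene RNA is itself unexplained, so they do not exclude it, and growth of the cultures, litter and cell density stay open and untested.

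Other splits of the libraries were fitted, with the real split always kept among those drawn, and the split by depth set kept for differentiation in wild type. For differentiation in wild type, the real split was the only 1 of 100 drawn of 126 with as many as 3158 genes, and the highest other, 2684, divides the libraries by depth set. Within depth sets, with the depth set as a term, the real split was again the only 1 of 60 with as many as 5267, and the highest other gave 3298. For the genotype effect averaged over cell types, 3 of 100 drawn of 315 splits, the real one included, gave as many as 398, and the highest gave 739, for wild-type myotubes 4 and 5 with dICR/dICR myoblasts 1 and 2, which are all shallow. Within depth sets, 2 of 60 splits, the real one included, gave as many as 2146, and the highest, 2777, set wild-type myoblasts 3 and 4 with wild-type myotubes 1 and 3 against the rest. In each, under 1 in 20 of the splits, the real one included, gave as many genes as the real one. This covers only a random division of these libraries. It does not exclude differences between cultures or animals, since the labels do not say whether replicates were separate. For the averaged effect other splits gave more genes than the real one, within depth sets as well. Over all libraries the depth sets are a structure of the samples that gives large counts by itself.

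Single libraries stood apart from the rest of their group in 13 of 143 groups of values tested, where chance gives about 7.2. In wild-type myotube 2, Wisp2 was 59.9 CPM (0.923 to 3.73 in the others), Islr 81 (1.42 to 8.96), Ctrb1 28.4 (1.69 to 5.55), Pde3b 14 (4.07 to 6.93), and the mean log2 CPM of the proliferating myoblast list 5.86 (5.11 to 5.24). In wild-type myotube 3, Kcnq1ot1 was 466 CPM (83.4 to 149 in the others), Tceal3 24.4 (9.18 to 11.6) and Dpp6 34.8 (3.06 to 10.9). In wild-type myotube 5, Osbp2 was 4.69 CPM (1.33 to 2.15) and Ramp1 67.6 (15.5 to 30.2). In wild-type myotube 1, Trpm5 was 0.724 CPM (0.407 to 0.492) and Cars 269 (117 to 157). Wisp2 was 0.0777 CPM in wild-type myoblast 2 and 0 in the other 3 wild-type myoblasts.

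The differentiation change differed between genotypes for 16 genes in the fit with the depth set as a term, by the test of that difference itself, 8 in each direction. Of these, the Y-linked Ddx3y and Eif2s3y follow from the depth term, which takes its shift from wild-type libraries that differ in Y-linked RNA. With no depth term the same test called 0 by edgeR, with 1643 at an unadjusted p under 0.05, and DESeq2 called 57 and limma voom 2.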

How the results depend on the processing

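Chosen after seeing the data were the settings without wild-type myoblasts 3 and 4, the crossed block, the size rule under the depth term, and the comparison of libraries from opposite depth sets. For the list tests, the surrogate variable, both other filters, thinning and only the groups compared were also added then. For H19 and Igf2 these and the test against a log2 fold change of 1 were added, and for the genotype effects in myoblasts and myotubes compared, these, library size alone, limma voom and the block. For this comparison and for H19 and Igf2 the values within depth sets were added as well. The remaining settings, and leaving out each library, were fixed before the data were examined, the depth sets only as a rule for a technical batch, since the sets themselves were defined from the data. Of 2397 values of 173 named-gene results under other settings, 2036 kept their direction and side of the threshold, 300 kept the direction but no longer passed, 30 newly passed and 31 changed sign. With 1 library left out, 1869 of 2249 kept both, 367 no longer passed, 3 newly passed and 10 changed sign. Most losses came with the test against a log2 fold change of 1 (81 of 173), the replicate block (65 of 173), thinning (52 of 165) and only the groups compared (30 of 145). Applied to the fit with the depth term, the size rule named 98 genes against 67, with 30 in both. Except where a construction is named below, the cause was not tested.

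Counts of called genes are given in the order genotype effect in myoblasts (5), genotype effect in myotubes (92), differentiation in wild type (3158), differentiation in dICR/dICR (24), difference in differentiation between genotypes (0) and genotype effect averaged over cell types (398). DESeq2 called 432, 1088, 4282, 1181, 57 and 1530, and limma voom with sample weights 3320, 533, 7025, 1193, 2 and 1505. With the depth set as a term the counts were 333, 425, 5267, 1262, 16 and 1925, and with 1 surrogate variable 241, 309, 4845, 1188, 1 and 1484. Within sets they were 868 in myoblasts, 601 in myotubes, 4804 (deep) and 1154 (shallow) for differentiation in wild type, and 2146 for the average. Thinning to the smallest library, which leaves fewer counts, gave 0, 20, 1687, 11, 0 and 108. The test against a log2 fold change of 1, which asks for a larger change, gave 0, 8, 403, 0, 0 and 38. Only the groups compared, which estimates the spread from fewer samples, gave 0, 1, 2587 and 2002, and could not be applied to the last 2. The replicate block gave 0, 3, 2376, 0, 0 and 66. The replicate numbers are not known to pair cultures, and wild-type libraries of the same number had correlations of 0.427, 0.518, -0.411 and 0.517, so the block is no evidence of pairing, and crossing the numbers in dICR/dICR gave 250 genes for its differentiation. RLE factors called 3 in myoblasts, library size alone 602 for the average, no low-count filter 1 in myoblasts and 41 for differentiation in dICR/dICR, and the 1 CPM filter 72 for the latter. Without wild-type myoblasts 3 and 4 the myoblast count was 31. Library size alone moved the median of all genes to 0.086 and 0.079 for the genotype effects in myoblasts and myotubes and 0.053 for the average, from -0.059, -0.056 and -0.086. RLE factors moved that of the difference in differentiation between genotypes from 0.037 to -0.131. With DESeq2 the genotype effects in myoblasts and myotubes had medians of 0.106 and -0.284, differentiation in dICR/dICR -0.276 and the difference -0.422.

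With 1 library left out the counts ranged from 0 to 6, from 1 to 919, from 1769 to 3574, from 0 to 78, stayed at 0, and ranged from 17 to 1090, in the same order. A group left with 1 library is assumed to vary like the others. For the gene list tests, 25 list calls over 4 contrasts became 0 with an estimated correlation and 11 with fry, which tests the genes of a list without comparing them with other genes, and ranged from 22 to 33 under the other settings and from 23 to 27 with 1 library left out. With the replicate block the sarcomere and myogenic medians of the genotype effects were -0.35 and -0.23 in myoblasts and -0.32 and -0.35 in myotubes. With limma voom they were -0.14 and -0.11 in myoblasts. The sarcomere median in myotubes was -0.59 with the depth term and -0.42 with the surrogate variable. For differentiation in dICR/dICR, library size alone gave medians of 0.24 for imprinted genes and 0.25 for the insulin-like growth factor list, and thinning ended the imprinted call (camera adjusted p = 0.112). The fibroblast call in myotubes ended with the 1 CPM filter (0.129), thinned (0.299) and with the block (0.137), and that in the difference between genotypes with RLE factors (0.0659), the 1 CPM filter (0.205) and thinned (0.529). The distal chromosome 7 median in myotubes was -0.44 with the depth term and -0.47 within sets.

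For H19 and Igf2: H19, genotype effect in myoblasts newly passed with DESeq2 (-7.29), limma voom (-5.77), the depth term (-7.7), within sets (-8.17), the surrogate variable (-7.46) and without wild-type myoblasts 3 and 4 (-5.28), and ranged from -7.68 to -6.9 with 1 library left out. For H19 and Igf2: H19, genotype effect in myotubes stood at -8.2 with the block, not past the threshold, and ranged from -9.09 to -8.74. For H19 and Igf2: Igf2, genotype effect in myoblasts was -0.27 within the shallow set and ranged from -0.43 to 1.02. For H19 and Igf2: Igf2, genotype effect in myotubes kept its sign and ranged from 0.41 to 2.07.

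The signs that turned were of genes that had not passed. Tspan32, genotype effect in myoblasts was 1.32 with limma voom, 0.93 with the block and 1.3 without wild-type myoblasts 3 and 4, Kcnq1, genotype effect in myoblasts 0.48, 0.06 and 0.33, and Lsp1, genotype effect in myoblasts 0.89, 0.36 and 1.16. Syt8, genotype effect in myoblasts was 0.04 with limma voom. Slc22a18, genotype effect in myoblasts was 3.66 with the depth term, 4.42 within sets and 0.1 with the surrogate variable, and the first 2 carry no direction, since the shallow wild-type myoblasts held 0 CPM. Nap1l4, genotype effect in myoblasts was 0 with no low-count filter, -0.07 with the depth term and -0.04 with the surrogate variable, and Cars, genotype effect in myoblasts -0.05 within sets. Mrpl23, genotype effect in myotubes was -0.48 with the block, -0.08 within sets and -0.7 with the surrogate variable. Tspan32, genotype effect in myotubes was 0.58 with the block, 0.27 with the depth term, 0.23 within sets and 0.4 with the surrogate variable, and Lsp1, genotype effect in myotubes 0.2, 0.08 and 0.31 with the block, the depth term and the surrogate variable. Tnni2, genotype effect in myotubes was 0.1 with the block and 0.1 with the surrogate variable, Trpm5, genotype effect in myotubes -0.11 with limma voom, and Kcnq1ot1, genotype effect in myotubes 0.21 with the block. With 1 library left out, Tspan32, genotype effect in myoblasts ranged from -0.73 to 0.54, Kcnq1ot1, genotype effect in myoblasts from -0.02 to 1.32, Nap1l4, genotype effect in myoblasts from -0.09 to 0.23, Cars, genotype effect in myoblasts from -0.01 to 0.41, Trpm5, genotype effect in myotubes from -0.9 to 0.81, Kcnq1ot1, genotype effect in myotubes from -0.96 to 0.35 and Slc22a18, genotype effect in myotubes from -2.15 to 0.05.

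The genotype effects in myoblasts and myotubes compared had r = -0.037 over all libraries, -0.267 with limma voom, -0.158 with no low-count filter, 0.163 with the 1 CPM filter, 0.149 thinned, 0.172 with only the groups compared, 0.209 with the block, 0.189 with the depth term, 0.255 within sets and 0.155 with the surrogate variable, and from -0.126 to 0.102 with 1 library left out. The genotype effect in myotubes against wild-type differentiation stayed negative on average, from -0.413 to -0.258 in the mean over divisions with 1 library left out. Its weakest single division turned positive without wild-type myoblasts 1 (0.088) or 2 (0.089), wild-type myotubes 1 (0.017) or 3 (0.096), or dICR/dICR myotube 1 (0.004). Depth limits the shallow libraries, which have 5.31 to 10.91 M counts, and small groups limit the dICR/dICR contrasts.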

Other observations

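Within sets, single genes of the imprinted, insulin-like growth factor, atrophy and other lists that were not called over all libraries also differed between genotypes. The shallow myoblast values are against wild-type myoblasts 3 and 4, which stand apart from 1 and 2. Igf2bp1, which encodes a binding protein of Igf2 and other messenger RNAs, rose by 1.60 ± 0.33 in shallow myoblasts (adjusted p = 0.0211, edgeR quasi-likelihood), and had 0.95 ± 0.29 in deep myotubes (adjusted p = 0.091). The chromatin gene Hmga2 was higher in both, by 1.46 ± 0.27 and 1.56 ± 0.23, although deep wild-type myoblasts held more of it (837.6 and 773.5 CPM) than dICR/dICR myoblasts (246.2 and 213.3 CPM), and Deptor, an inhibitor of mTOR, fell in both, by 0.99 ± 0.25 and 0.92 ± 0.23. Igfbp4 (-4.62 ± 0.97) and Igfbp3 (-1.35 ± 0.35) were lower in shallow dICR/dICR myoblasts, at levels near those of wild-type myoblasts 1 and 2 (Igfbp3 at 65.9 and 51.08 CPM against 51.02 and 52.6 CPM), and Igfbp5 (1.95 ± 0.44) and the fatty acid carrier gene Cd36 (2 ± 0.31) rose in deep myotubes. Pdk4, a regulator of glucose oxidation, fell in shallow myoblasts (-1.06 ± 0.26) and rose in deep myotubes (1.39 ± 0.23), and this difference was not tested within sets. Among imprinted genes outside distal chromosome 7, Asb4 (-3.40 ± 0.50), Gatm (-1.78 ± 0.32), Ddc (-1.32 ± 0.24) and Magel2 (-3.54 ± 0.88) were lower in shallow dICR/dICR myoblasts, and none passed in deep myotubes by edgeR. Wild-type myoblasts 3 and 4 carry much of this, as the mean log2 CPM of the list was 4.88 and 4.88 in them, 3.72 and 3.67 in wild-type myoblasts 1 and 2, and 4.12 and 3.56 in dICR/dICR.

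Lists not called in either genotype effect over all libraries are given as median log2 fold changes in myoblasts and then myotubes, with camera adjusted p in the same order. They were imprinted genes outside distal chromosome 7 (-0.47 and -0.20, 0.0745 and 0.374), ERK pathway output (-0.62 and -0.19, 0.146 and 0.806), the insulin-like growth factor list (-0.20 and -0.01, 0.231 and 0.863) and atrophy and FoxO targets (-0.31 and 0.08, 0.246 and 0.806). Integrated stress and heat shock had 0.39 and 0.08 (0.0997 and 0.292), nuclear long noncoding RNAs 0.61 and -0.97 (0.589 and 0.354) and sex-linked check genes 1.30 and -0.19 (0.173 and 0.811). Markers of other cell types were adipocyte (-0.11 and -0.30, 0.589 and 0.811), endothelial (-0.13 and -1.42, 0.589 and 0.251), macrophage (0.48 and -2.93, 0.581 and 0.127), Schwann cell (1.00 and -1.29, 0.411 and 0.354) and smooth muscle (-0.32 and -0.78, 0.952 and 0.251). Camera gave the direction up where the median was below 0 for the adipocyte list in both cell types, the endothelial list in myoblasts, and the insulin-like growth factor and sex-linked lists in myotubes. In wild-type differentiation the lists not called, besides proliferating myoblast genes (camera adjusted p = 0.446), were imprinted genes (0.0972), atrophy (0.1), transforming growth factor beta (0.29), stress (0.557), adipocyte (0.964), endothelial (0.864, direction down with a median of 0.27), macrophage (0.779), Schwann cell (0.643), noncoding RNA (0.446) and sex-linked (0.446).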
